A study of Mus musculus with 2 samples.

How the data were processed

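USF1 ChIP-seq of MEL cells was measured in 2 replicates of 1 group, numbered as in the labels, and both replicates cite the same stock record. No control library was analysed here. The deposited data were 6 peak lists in narrowPeak layout without header lines, and the text files deposited beside them name the type, the assembly and the origin of each. Per these deposited texts, the authors made a list of peaks and background entries for each replicate on mm10 (300000 entries each). They made a list of the same kind from both replicates pooled (139383). From these came an optimal-threshold list (18096) and a conservative-threshold list (15897), by IDR, which compares the ranks of peaks between lists. Each mm10 list was also derived from a further file whose kind is not given in the sources used here, which may be a control or a list of excluded regions. A further list of 13023 peaks on mm9 was derived from the alignments of both replicates. The peak caller, its version and the IDR threshold are not given in the sources used here.

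The signal of each peak is the authors' own value from their peak caller. Its scale is not given in the sources used here, so it served only to rank, describe or compare peaks within 1 list. The deposited lists also carry a −log10 q-value and the offset of the summit, and the deposited score column was not used for any test. The signals of the lists are on different scales, with a maximum over median of 15.3 in the optimal list and 159.5 in the mm9 list, so signals were never set against each other across lists. Of the conservative peaks, 13835 (87.0%) shared a summit with the optimal list. The lists hold no read numbers, so the depth per replicate is unknown, and the precision of each share follows from the number of peaks, genes or sites behind it. Exact (Clopper-Pearson) 95% intervals are given for shares.

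The genome sequence and transcript annotation used here (GENCODE vM1) are of mm9, and the RefSeq gene table is of GRCm38, the assembly of mm10. No coordinate was converted between builds. Results on genes used the mm10 optimal list with the RefSeq gene table. That table gives no strand, so strand was taken from GENCODE by symbol for 18392 genes and by synonym for 2149, and 1346 had none. This left 20522 of 21887 protein-coding genes (93.8%) on the chromosomes that hold peaks, each with 1 start, its annotated 5' end. A gene was bound when a summit lay within 1 kb of that 5' end, a distal peak lay more than 10 kb from every such end, and 496 peaks were counted for more than 1 gene. Results on sequence used the mm9 list, the mm9 genome and the starts of 51723 coding transcripts. The design fixed before the data were examined had named the optimal list for these sequence results as well, and the mm9 list took its place because no mm10 sequence was used here. CpG content within 500 bp of the 5' end, and the presence of CACGTG within 1 kb of it (the promoter window), came from the mm9 sequence. They were assigned by gene symbol and found for 98.8% of the genes.

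The overlap of replicates compared the strongest 15897 peaks of each, the size of the conservative list, by summits within 100 bp, against 100 random shifts. Rank correlation used the optimal-list peaks with a match in both replicate lists. The promoter share was compared with 1000 random placements on the same chromosomes. Each of 26 gene lists and 21 sequence words was fixed before the data were examined. Lists were tested by two-sided Fisher's exact tests against all other genes tested, and words by two-sided exact McNemar tests of the summit window (50 bp to each side) against windows 500 bp to the left and to the right, keeping the larger p. Both were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Signals with and without CACGTG were compared with 10000 permutations. A CACGTG site was called occupied when it lay within 50 bp of a summit. Computed p-values below 1e-300 were recorded as 1e-300. Peaks and genes are not independent replicates, so these p-values describe these lists.

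The genes named were chosen by a rule fixed before the data were examined. It takes the 10 strongest promoter peaks, the 5 strongest distal peaks, up to 4 members of each gene list by peak signal or, in lists with fewer, these and up to 2 members without a peak, and always Usf1, Usf2, Myc, Gata1, Klf1, Tal1, Hba-a1, Hbb-bs and Hbb-bt. Of the 93 named genes with a promoter peak, each counted once, 93 also had one in each replicate alone and 85 in the mm9 list. The rule favours strong peaks, so these counts do not stand for all bound genes. Of all 4370 genes with a promoter peak, 3072 also had one in the mm9 list.

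Alternatives were the conservative threshold, the mm9 list, each replicate alone, other distances, windows and list sizes, stratification of genes by 10 bins of promoter CpG content (Mantel-Haenszel test), and only genes with CACGTG in the promoter window. The word test, the replicate overlap, the gene list test, the stratified test and the signal comparison were tested on simulated data. The other procedures were not. A word removed from all windows and then planted in 40.0% of them was found in 40.0%, which checks only the search. A simulated replicate overlap of 70.94% was measured as 70.98%, and a simulated 2-fold signal ratio as 2.07. In the gene list simulation over 21887 genes, 100% of changed lists were recovered and 5.0% of unchanged lists were called. In a single simulation with no effect within strata, the stratified odds ratio was 0.867, against 1.17 without strata. How far such a value strays by sampling was not measured. The analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.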

Results

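USF1 is a bHLH-zipper transcription factor that binds the E-box CACGTG. Its binding across the genome was mapped by ChIP-seq, in which DNA cross-linked to the protein is recovered with an antibody and sequenced, in MEL cells, a mouse erythroleukemia line that the labels call the counterpart of human K562. The series held 1 group of 2 replicates and no untreated or control sample, so the questions it can answer are where USF1 was bound, at which sequences and near which genes. The labels tie both replicates to the same stock record, so the spread between them may be technical. The optimal-threshold list made by the authors from both replicates held 18096 peaks on mm10, with a median width of 320 bp, and a separate combined list on mm9 held 13023 peaks. Read numbers are not part of these lists, so the depth of each replicate is unknown, and confidence intervals on shares of peaks or genes cover counting error only.

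Both replicates placed their strongest USF1 peaks at the same positions. Of the strongest 1000 peaks of replicate 1, 86.1% (95% exact interval 83.8 to 88.2) had a summit within 100 bp of a summit among the strongest 1000 of replicate 2, and 100% matched an entry somewhere in the full list of replicate 2. Over the strongest 15897 peaks of each replicate the shared fraction was 70.3% (95% exact interval 69.5 to 71.0), against 0.142% when summits were moved at random along their chromosomes. Across the 16428 optimal-list peaks found in both replicate lists, 90.8% of that list, Spearman's rho of the replicate signals was 0.803 (bootstrap 95% interval 0.796 to 0.811). The optimal list was itself made by IDR from these same replicates, so this correlation describes the list and is no separate evidence of agreement. Not every peak of the list was found in both replicates. For 1269 peaks no replicate 1 entry lay within 100 bp, and for 472 no replicate 2 entry. The shared fraction depended on how many peaks were compared and was 52.8% over the strongest 31794.

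The strongest promoter peak of the optimal list lay at Ndel1, which encodes a regulator of the dynein motor. It spanned chromosome 11, 68853043 to 68853372 (mm10), with a signal of 669.7 and its summit 67 bp upstream of the gene's 5' end, and it ranked 1 in both replicates. Aldh3a2, a fatty aldehyde dehydrogenase gene, followed with a signal of 639.8 at chromosome 11, 61267036 to 61267396, 310 bp downstream of its 5' end. Wdr19, a gene of intraflagellar transport, had a peak of signal 636 at chromosome 5, 65199396 to 65199746, and Med13, a subunit of the Mediator kinase module, one of 635 at chromosome 11, 86358149 to 86358483. Dcaf13 on chromosome 15 (629.6), the SUMO ligase gene Pias4 on chromosome 10 (618.5), Neurl2 on chromosome 2 (617), Ccnyl1 on chromosome 1 (613), Ubxn1 on chromosome 19 (612) and Faf1 on chromosome 4 (611) completed the 10 strongest promoter peaks. All 10 ranked among the strongest 74 peaks of replicate 1 and the strongest 86 of replicate 2. In the mm9 list, where the order differed and these peaks ranked from 14 (Aldh3a2) to 185 (Ndel1), each of these promoters held CACGTG within 50 bp of the summit. The mm9 word with its flanks was GTCACGTGGA at Ndel1 (chromosome 11, 68666706 to 68666711 for the 6 central bases), ATCACGTGAC at Wdr19 and GTCACGTGAC at Faf1. Chromosome 11, which carried 3 of these genes, also held 1.55 times (replicate 1) and 1.61 times (replicate 2) the median autosomal density of weak distal background entries.

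Strong binding was also found far from genes' 5' ends. The strongest peak more than 10 kb from any protein-coding 5' end lay at chromosome 5, 122625054 to 122625382 (mm10), with a signal of 614, inside the gene Gm32988 and 10674 bp from the 5' end of Ift81. The next lay at chromosome 18, 23803744 to 23804064, with a signal of 603, inside Mapre2 and 51578 bp from its 5' end. A peak of signal 601 at chromosome 15, 38244852 to 38245189, was in no annotated gene and 25823 bp from Odf1. On chromosome 19 a peak at 44930815 to 44931127 (signal 594) lay inside Slf2, 12468 bp from its 5' end, and one at 29063851 to 29064204 (signal 593) lay in no gene, 15947 bp from Ak3.

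USF1 peaks were concentrated at promoters, although most lay elsewhere. Of the 18096 peaks, 4491 (24.8%, 95% exact interval 24.2 to 25.5) had a summit within 1 kb of a protein-coding gene's 5' end, 15.2 times the mean of 1.63% over 1000 random placements on the same chromosomes. No placement exceeded 1.91% (one-sided permutation p = 0.001, the smallest these placements can give). Gene 3' ends, by comparison, held 3.44% of the summits. The promoter summits lay a median of 130 bp from the 5' end. A further 9432 peaks (52.1%) were more than 10 kb from any such 5' end, and 4173 (23.1%) lay between. Median signals were 50.9 at promoters, 43.9 between and 41.7 at distal sites. The promoter share was 48.8% over the strongest 1809 peaks and 58.9% among the strongest 1000 peaks, and a limit of 5 kb raised it to 38.9%. In the mm9 list, introns held 31.6% of summits against 35.9% of random positions, intergenic sequence 34.8% against 58.8%, and coding exons 0.791% against 1.24%.

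USF1 peaks lay at the promoters of 4370 of 20522 genes tested (21.3%, 95% exact interval 20.7 to 21.9). Genes of the lysosome and of its acidification stood far above that level. Not every promoter peak held CACGTG or its variant CATGTG within 50 bp of the summit. In the mm9 list 1640 of 4036 promoter peaks held neither, among them peaks at Ncl, Ftl1 and Fdps, named below. Direct binding of USF1 at such peaks was not tested. The vacuolar H+-ATPase, the proton pump that acidifies lysosomes, had a promoter peak at 15 of 16 genes (93.8%, odds ratio 55.6, exact adjusted p = 9.15e-09), with signals of 610.2 at Atp6v1c1, 563 at Atp6v1h and 557 at Atp6v0b. Among lysosomal genes 31 of 41 were bound (75.6%, odds ratio 11.5, exact adjusted p = 4.06e-12). They included Ctsa, encoding cathepsin A, which shares its peak of signal 617 with Neurl2, the hexosaminidase gene Hexa (592) and Naglu (585). Gba, which encodes glucocerebrosidase, had a peak of signal 563 that ranked 128 in the optimal list and 1 in the mm9 list. Of genes of autophagy and mTORC1 regulation 28 of 44 were bound (63.6%, odds ratio 6.50, exact adjusted p = 1.02e-08), with signals of 604 at Atg3, 565 at Vps11 and 547 at Uvrag. Genes of the unfolded protein response were bound at 19 of 27 promoters (70.4%, odds ratio 8.81, exact adjusted p = 3.20e-07), among them Derl1 (546), Dnajb11 (514) and Atf6b (490.2). The median peak signal over these 19 was 59.7. The stress-response factor gene Atf4 had a signal of 486 in the optimal list but no promoter peak in the mm9 list. These p-values are from two-sided Fisher's exact tests against all other genes tested, adjusted over 26 lists by the Benjamini-Hochberg method. All 4 calls held when genes were stratified by promoter CpG content and among genes with CACGTG in the promoter window.

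**Figure D1:**
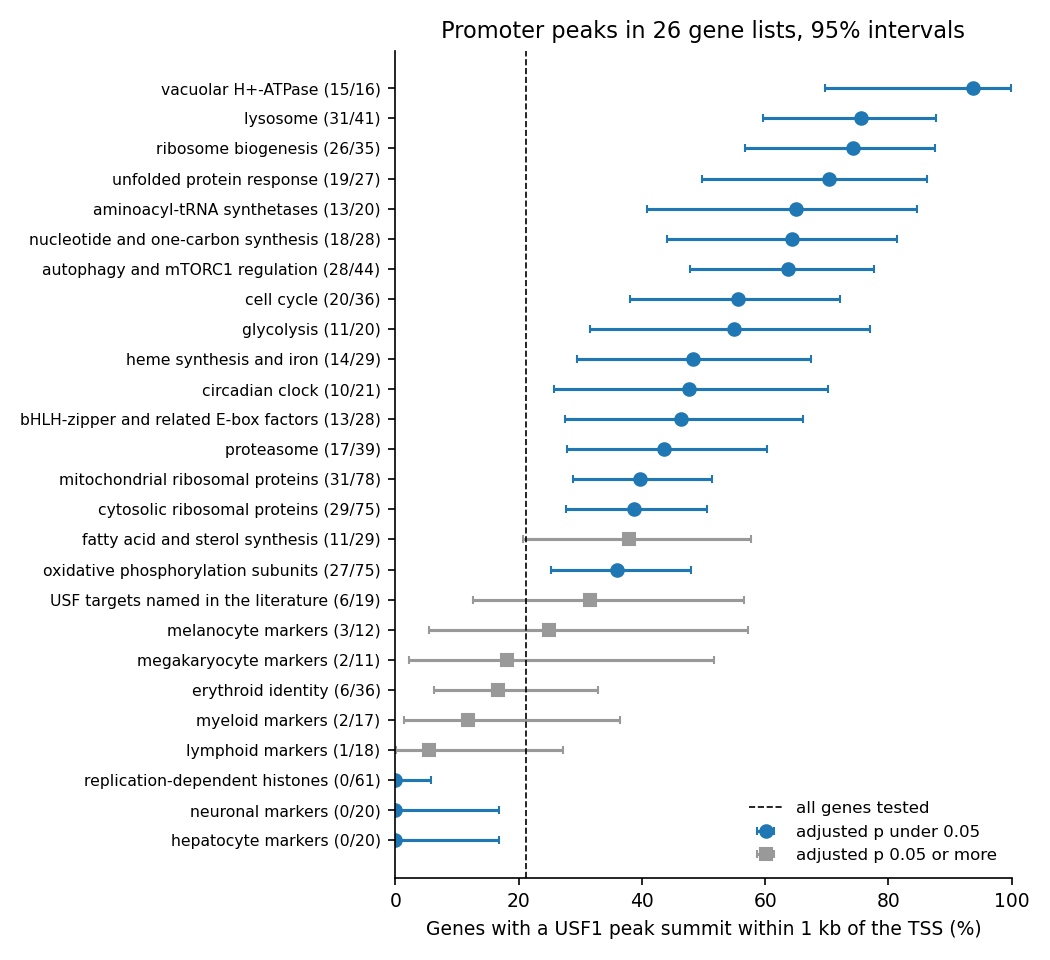
Share of genes in each of 26 lists with a USF1 peak summit within 1 kb of the 5' end (points, with 95% exact intervals; bound and tested genes in brackets; blue, adjusted p under 0.05 by two-sided Fisher's exact test). The dashed line marks the 21.3% of all genes tested, and the vacuolar H+-ATPase lies highest at 93.8%.

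Growth and biosynthesis genes were also bound more often than other genes. Ribosome biogenesis genes had a peak at 26 of 35 promoters (74.3%, odds ratio 10.7, exact adjusted p = 3.81e-10), with signals of 488 at the nucleolin gene Ncl, 484 at Utp20 and 439 at Nop2. Nucleotide and one-carbon synthesis genes were bound at 18 of 28 promoters (64.3%, odds ratio 6.68, exact adjusted p = 4.10e-06), among them Shmt1 (533), Atic (507) and Nme1 (494). Aminoacyl-tRNA synthetase genes were bound at 13 of 20 promoters (65.0%, odds ratio 6.88, exact adjusted p = 8.84e-05), but with a median peak signal of 36.1. Of 37 symbols in this list, these 20 were among the genes tested. Their strongest peak was at Tars (271). Cell cycle genes were bound at 20 of 36 promoters (55.6%, odds ratio 4.64, exact adjusted p = 2.32e-05), including Cdk4 (538), E2f1 (rank 252) and the replicative helicase gene Mcm2 (529). Glycolysis genes were bound at 11 of 20 promoters (55.0%, odds ratio 4.53, exact adjusted p = 0.00213), with signals of 206 at Tpi1 and 186 at Pfkm. Among genes whose promoter window held CACGTG, where fewer genes could be tested, these last 3 lists did not pass the test. Aminoacyl-tRNA synthetases had 4 of 6 bound there (odds ratio 3.02, exact adjusted p = 0.292), cell cycle genes 10 of 16 (2.52, exact adjusted p = 0.165) and glycolysis genes 8 of 11 (4.03, exact adjusted p = 0.105).

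Heme and iron genes were bound more often than other genes, whereas the erythroid identity genes did not pass the test. The difference between these lists was not tested. Peaks lay at 14 of 29 promoters of heme synthesis and iron handling (48.3%, odds ratio 3.46, exact adjusted p = 0.00226). They included the heme synthesis genes Urod (539) and Uros (374), the heme oxygenase gene Hmox1 (438) and the ferritin light chain gene Ftl1 (167). Over the 14 bound genes the median peak signal was 43.3, against 50.9 over all promoter peaks. Of the 12 genes of this list with CACGTG in the promoter window 8 were bound (odds ratio 3.02), which did not pass the test (exact adjusted p = 0.165). Erythroid identity genes had 6 bound promoters of 36 (16.7%, 95% exact interval 6.37 to 32.8, exact adjusted p = 0.740). Their odds ratio was 0.739, but 1.16 with CpG content stratified, 1.51 within 5 kb (14 of 36) and 1.42 in the mm9 list (9 of 36). None of these passed the test. With CpG content stratified the heme and iron list had 2.43 (Mantel-Haenszel chi-square test, adjusted p = 0.0346). Promoter CpG (observed over expected) had a median of 0.270 in the erythroid and 0.674 in the heme and iron list. The strongest of the 6 bound erythroid genes was Epb41, encoding the membrane skeleton protein 4.1 (299), followed by the spectrin gene Sptb with a signal of 66.8. Klf1, an erythroid master regulator, had a weak peak 46 bp upstream of its 5' end (signal 39.9, rank 9766) and Lyl1 had a peak of signal 33.1, but neither promoter had a peak in the mm9 list. The nearest summit lay 6606 bp from the 5' end of Tal1 and 3954 bp from that of Hba-a1, an alpha globin gene, where the nearest peak had a signal of 309. The nearest summit to the 5' end of Gata1 was 28668 bp away, but the mm9 list held a peak of rank 4303 at a transcript start of this gene. The beta globin genes Hbb-bs and Hbb-bt were not among the genes tested. Other genes of the beta globin family, Hbb-b1, Hbb-b2, Hbb-bh1 and Hbb-y, were tested and had no promoter peak.

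Bound promoters were also more frequent in the mitochondrial, ribosomal, proteasome, clock and E-box factor lists, with smaller odds ratios. Mitochondrial ribosomal proteins had 31 of 78 bound promoters (39.7%, odds ratio 2.45, exact adjusted p = 0.000610), with 499.8 at Mrpl27 and 479.6 at Mrps18c. Cytosolic ribosomal proteins had 29 of 75 (38.7%, odds ratio 2.34, exact adjusted p = 0.00137), with 543 at Rpl23 and 379.9 at Rps28, whose peak also lay at Ndufa7. Subunits of oxidative phosphorylation had 27 of 75 (36.0%, odds ratio 2.09, exact adjusted p = 0.00678), with 319.5 at Atp5g1. The proteasome had 17 of 39 (43.6%, odds ratio 2.86, exact adjusted p = 0.00457), with 437 at Psmb3 and 433 at Psmd9. Circadian clock genes had 10 of 21 (47.6%, odds ratio 3.37, exact adjusted p = 0.00995), including Tef (593), Ciart (561) and Per1 (407). The strongest promoter peak at Ciart ranked 142 in the optimal list but 11234 in the mm9 list. Peaks were not matched between builds, so these ranks, and those given for Mga below, may belong to different peaks. Genes of bHLH-zipper and related E-box factors had 13 of 28 (46.4%, odds ratio 3.21, exact adjusted p = 0.00666), among them the MYC partner gene Max (497), Mlx (552) and Mga (369, rank 1117 in the optimal list and 11248 in the mm9 list). Usf2, the paralog of Usf1, had a peak 59 bp downstream of its 5' end (signal 177, rank 2827), whereas the nearest summits lay 65092 bp from Usf1 and 61123 bp from Myc. Stratified by promoter CpG content in a Mantel-Haenszel chi-square test, these 6 lists did not pass. Odds ratios were then 1.42, 1.22, 1.24, 1.83, 2.08 and 1.92 in the order above (chi-square adjusted p = 0.249, 0.537, 0.509, 0.182, 0.205 and 0.223). Among genes with CACGTG in the promoter window, oxidative phosphorylation was above the other genes (13 of 17, exact adjusted p = 0.0168). The other 5 did not pass there, with fewer genes and odds ratios of 2.02, 1.98, 1.73, 2.27 and 2.11 (exact adjusted p = 0.223, 0.165, 0.341, 0.289 and 0.298).

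The remaining lists did not pass the test for more bound promoters. Fatty acid and sterol synthesis genes had 11 bound promoters of 29 (37.9%, odds ratio 2.26, exact adjusted p = 0.0506), with peaks at Insig1 (472), Sc5d (451) and Fdps (222). At the conservative threshold this list passed the test (exact adjusted p = 0.0147), as it did in replicate 1 alone (0.00135), within 500 bp (0.0443), within 5 kb (0.00314) and in the mm9 list (0.0103). It did not pass in replicate 2 alone (exact adjusted p = 0.0850), among genes with CACGTG in the promoter window (exact adjusted p = 0.238) or with CpG content stratified (odds ratio 1.497, Mantel-Haenszel chi-square test, adjusted p = 0.509). Of the USF targets named in the literature 6 of 19 were bound (31.6%, exact adjusted p = 0.315), including Cdk4, Hmox1 and the metallothionein genes Mt2 (430.4) and Mt1 (239.7). The melanocyte list had 3 of 12 (exact adjusted p = 0.756), with Mc1r the strongest at 161 and no peak at Tyr or Tyrp1. Megakaryocyte markers had 2 of 11 (exact adjusted p = 1), Gp1ba (281) and Treml1 (74.1). Myeloid markers had 2 of 17 (exact adjusted p = 0.624), Cd68 (49.8) and Cebpa (37.7, with no promoter peak in the mm9 list). Lymphoid markers had 1 of 18 (exact adjusted p = 0.183), Cd3d (22.5), but were below the other genes in the mm9 list (0 of 18, exact adjusted p = 0.0426).

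No replication-dependent histone gene was bound among 61 (exact adjusted p = 3.38e-06, upper 95% exact limit 5.87%), including H2ac20 and H2ac21. At the conservative threshold, and in each replicate alone, 1 of 61 was bound, which still passed the test for fewer bound promoters. The mm9 list held a peak of rank 8979 at H2ac20 and 2 bound histone genes in all. Entries of any strength were also rare there, since 3.33% of 60 histone genes had an entry of the pooled list within 1 kb, against 55.9% of genes of like CpG content without a peak. The hepatocyte and neuronal markers, such as Alb, Apoa1, Syn1 and Snap25, had 0 bound promoters of 20 each (exact adjusted p = 0.0171, upper 95% exact limit 16.8%). The same counts of 0 did not pass the test with CpG content stratified (Mantel-Haenszel chi-square test, adjusted p = 0.509 and 0.0584). Within 5 kb 4 hepatocyte and 3 neuronal genes had a peak (Fisher's exact test, adjusted p = 0.550 and 0.286), and without replicate 1 there was 1 bound neuronal gene (adjusted p = 0.193). Only 6 histone, 4 hepatocyte and 7 neuronal genes held CACGTG in the promoter window, and 0 of them were bound, too few to pass the test (exact adjusted p = 0.175, 0.238 and 0.135).

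The textbook E-box was the leading word under the summits. In the mm9 list 5592 of 13023 peaks (42.9%, 95% exact interval 42.1 to 43.8) held CACGTG within 50 bp of the summit, against 1.57% of windows 500 bp to either side, a 27.3-fold excess (two-sided exact McNemar test, p at the smallest value recorded, 1e-300). The nearest CACGTG was centred a median of 10.5 bp from the summit (quartiles 4.5 and 16.5 bp) over the 6008 peaks that held it within 250 bp. The variant CATGTG was also frequent, at 36.8% of summits (5.02-fold over flanks), and its extended form TCATGTGA, known as the M-box, stood at 13.9% (45.8-fold). Outside the E-boxes, the GATA word AGATAA occurred at 12.0% of summits (2.40-fold, exact adjusted p = 9.27e-88), the ETS word CCGGAAG at 3.52% (4.24-fold, exact adjusted p = 9.57e-50) and the AP-1 site at 4.92% (3.16-fold, exact adjusted p = 1.54e-52). The GATA word was not more frequent than in flanks among the strongest 1000 peaks (4.6%, 1.03-fold, exact adjusted p = 0.832) or at promoter summits (0.922-fold, exact adjusted p = 0.7503). Of 21 words tested, 18 were more frequent at summits than in flanks. The other 3 were CATATG and the permuted palindromes ACCGGT and GTCGAC. The remaining permuted palindrome, TGCGCA, was enriched (2.92%, 3.57-fold, exact adjusted p = 3.32e-37).

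**Figure D2:**
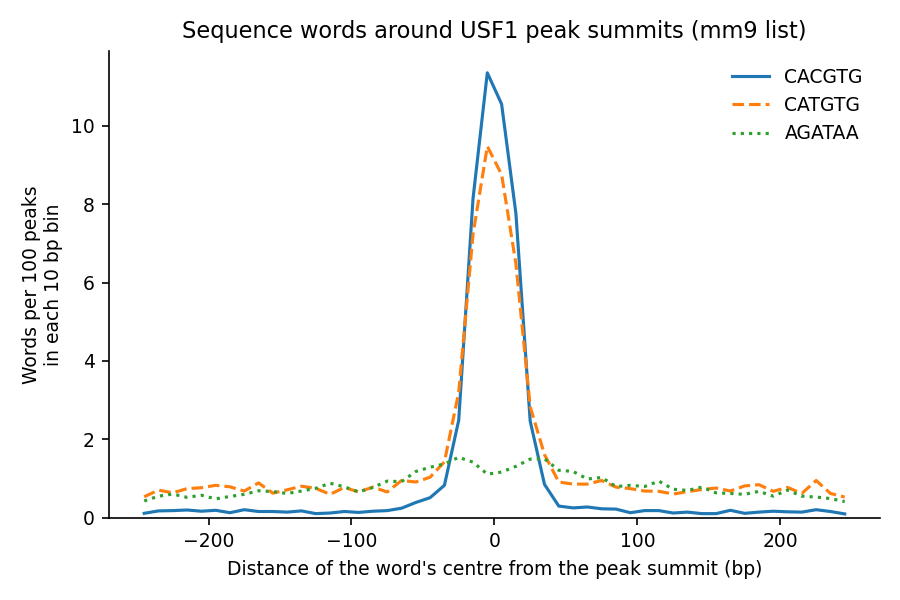
Number of CACGTG, CATGTG and AGATAA words per 100 peaks in bins of 10 bp, against the distance in bp of the word's centre from the summit of 13023 peaks of the mm9 list. CACGTG reaches 11.3 words per 100 peaks just left of the summit, whereas AGATAA peaks to both sides, at 1.54 and 1.51 words, and is at 1.11 next to the summit.

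Stronger peaks held the E-box more often. CACGTG was present in 81.4% of the strongest 1302 peaks of the mm9 list (95% exact interval 79.2 to 83.5) and in 26.1% of the weakest 1303 (23.7 to 28.6). The share of peaks with neither CACGTG nor CATGTG went from 5.45% to 41.1% between the same sets. The median signal was 152 for peaks with CACGTG and 76.0 for peaks without, a ratio of 2.00 (two-sided permutation p = 0.0001, the smallest that 10000 permutations can give). At promoters the ratio was 4.99, with medians of 356 and 71.4, and at distal peaks it was 1.46, with medians of 115 and 78.7; the difference between these ratios was not tested.

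**Figure D3:**
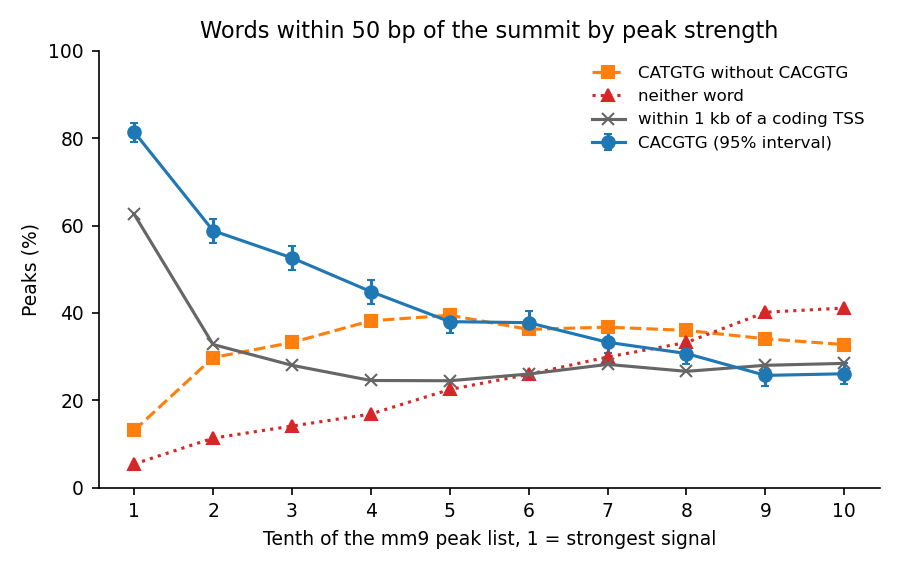
Share of peaks (percent) with CACGTG (circles, with 95% exact intervals), with CATGTG but not CACGTG, with neither word, and within 1 kb of a coding transcript start, in 10 equal bins of the mm9 list ordered by signal. CACGTG goes from 81.4% of the strongest bin to 26.1% of the weakest, and peaks with neither word from 5.45% to 41.1%.

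Promoter and distal peaks differed in the form of E-box they held. CACGTG was at 47.0% of 4036 promoter peaks and 41.0% of 5758 distal peaks (odds ratio 1.27, 95% interval 1.17 to 1.38, two-sided Fisher's exact test p = 5.89e-09). CATGTG without CACGTG was at 12.4% of promoter peaks and 43.1% of distal peaks (odds ratio 0.187, exact p = 1.57e-249). Either word was present at 59.4% of promoter and 84.1% of distal peaks. Peaks with CATGTG alone had a median signal of 88.9, and 57.8% of them were distal. The GATA word was at 3.37% of promoter and 16.6% of distal summits (exact adjusted p = 1.99e-106), and the M-box at 4.29% and 19.1% (exact adjusted p = 9.71e-115). The ETS word showed the opposite order, at 9.04% and 0.990% (exact adjusted p = 6.70e-86), as did the GC box at 31.5% and 3.56%. Flanks of promoter peaks also held the GC box more often (11.7% left, 11.6% right) than those of distal peaks (1.98% and 1.65%). The permuted palindromes had the same order, with TGCGCA at 6.96% and 1.04%, ACCGGT at 1.07% and 0.382% and GTCGAC at 0.644% and 0.122%. This order is therefore not particular to factor sites.

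Most CACGTG words in the genome were not under a peak, and the bases beside the word marked those that were. Of 262836 CACGTG sites on mm9, 5900 (2.24%) lay within 50 bp of a summit. Sites with T before and A after, TCACGTGA, were occupied in 7.86% of 13361 cases, against 1.37% of 156906 sites with neither base, a ratio of 5.76 (two-sided Fisher's exact test, p at the smallest value recorded, 1e-300). Within 1 kb of a coding transcript start the shares were 53.1% and 13.4% (ratio 3.96, exact p = 5.21e-112). The 10-base word GTCACGTGAC, the textbook USF site, was occupied at 22.0% of 1592 sites, and ACACGTGT at 0.492% of 23167. Location alone also separated the sites, with 20.9% occupied within 1 kb of a transcript start and 1.21% at more than 10 kb.

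**Figure D4:**
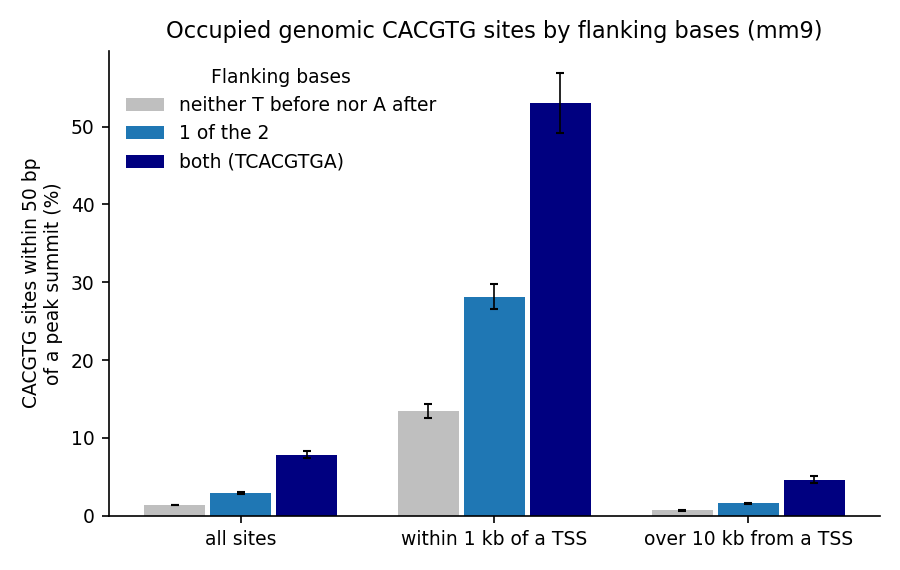
Percent of genomic CACGTG sites (mm9) within 50 bp of a USF1 summit (bars, with 95% exact intervals), for sites with neither, 1 or both of T before and A after the word, over all sites, near a coding transcript start and far from any. Sites with both bases reach 53.1% within 1 kb of a start, and sites with neither base more than 10 kb away are at 0.688%.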

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

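Alternatives chosen after seeing the data were the mm9 list with every coding transcript start, for the promoter share and the gene lists, and windows of 25 bp and the strongest 1000 peaks, for the enriched words. The overlap of the replicates' strongest peaks was 66.1% with summits within 50 bp, 72.3% within 250 bp, 72.5% with intervals that overlap, 86.1% over the strongest 1000 peaks and 52.8% with the number of peaks doubled. The rank correlation of replicate signals was 0.872 at the conservative threshold, 0.831 with summits within 50 bp and 0.667 over the strongest 1000 peaks, where the range of signals is narrower. The number of gene lists above the other genes was 10 with CpG content stratified and 7 among genes with CACGTG in the promoter window, against 16 in the main test. Lists below the other genes were 3 in the main test, 2 without replicate 1, 1 within 5 kb, 1 with CpG content stratified, 0 among genes with CACGTG and 4 in the mm9 list. The same 16 lists were above at the conservative threshold, in each replicate alone, within 500 bp, within 5 kb and in the mm9 list, with totals of 16 to 17. With each replicate left out in turn, the promoter share ranged from 22.8% to 29.0% and the gene lists above from 16 to 17. The promoter share was above random placements under all alternatives run, as were the enrichment of CACGTG at summits, the signal ratio, the promoter excess of CACGTG and the flank preference in direction and side of the threshold. The number of enriched words, 18 in the main test, was 19 with windows of 100 bp or flanks 1000 bp away, 16 with windows of 25 bp and 12 over the strongest 1000 peaks, where the GATA word was not enriched. The cause of the shifts in overlap and correlation was not tested. The conservative threshold and the left-out replicates were not run for the E-box share, the enriched words, the signal ratio, the promoter against distal comparison or the flank preference, because no mm10 sequence was used here. Depth is unknown, so its effect on weak peaks could not be measured.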

Other observations

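Tests chosen only after the result was seen were the share of E-box-free peaks in the strongest 1302, the stratified odds ratio for chromosome 11, and the share of histone genes with a background entry; the last was first written as a test of read loss between gene copies and re-assigned once its value was known, when the test of word uniqueness was added.

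Peaks with neither CACGTG nor CATGTG held several other words more often than peaks with CACGTG, both at promoters and at distal sites. A difference between the locations was not tested. The class with neither word also had weaker peaks (median signal 63.7 against 152). The comparisons were not matched for signal, so the differences may go with peak strength. At 1640 promoter peaks of this class, the E-box variant CACGCG was at 21.9% of summits, against 3.14% in the flanks and 6.49% at promoter peaks with CACGTG (odds ratio 4.04, exact adjusted p = 3.35e-40, two-sided Fisher's exact test). The CCAAT box was at 25.4% against 16.0% (exact adjusted p = 2.69e-11). The CRE, the site of the CREB and ATF factors, was at 3.17% against 1.27% (exact adjusted p = 0.000260). The permuted palindrome TGCGCA, a control word, was also higher, at 9.57% against 5.44% (exact adjusted p = 8.25e-06). The control palindromes ACCGGT and GTCGAC did not differ (exact adjusted p = 0.907 and 0.830). At distal peaks of this class, the GATA word was at 23.0% against 14.0% of distal peaks with CACGTG (odds ratio 1.83, exact adjusted p = 7.14e-09). The E-boxes CAGGTG (31.9% against 7.45%, exact adjusted p = 1.64e-63) and CAGCTG (19.8% against 7.07%, exact adjusted p = 5.17e-23) were also more frequent there. Some words were raised at both locations, with CAGGTG at 15.7% against 5.96% at promoters (exact adjusted p = 1.11e-20), CACGCG at 2.84% against 0.847% at distal sites (exact adjusted p = 0.000114) and CCAAT at 17.0% against 12.96% there (exact adjusted p = 0.00600).

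Flanking bases 2 positions away from the word went with large differences in occupancy. Of 12436 genomic TCCACGTGAA sites only 6 (0.0482%) were occupied, whereas its inner 8 bases CCACGTGA were occupied at 3.60% of 40671 sites. This word was far more frequent than GCCACGTGAA (1656 sites), CCCACGTGAA (1765) and ACCACGTGAA (1831), which were occupied at 1.39%, 0.850% and 1.69%. An effect of its flanking bases therefore cannot be told apart from another trait of its many copies. The word was singled out after its values were seen, and no explanation was tested.

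Peaks with neither E-box word lay at promoters in 52.3% of cases, against 33.9% of peaks with CACGTG. A summit placed off the E-box was argued against, since only 5.87% of these peaks held CACGTG at 51 to 250 bp from the summit, against 6.54% in the same windows 1000 bp away. Weak peaks were not argued against as the main source of this class. It made up 24.1% of the mm9 list but 5.45% of its strongest 1302 peaks (95% exact interval 4.28 to 6.83). Its median signal was 63.7, against 152 for peaks with CACGTG. Not every peak of the class was weak, since 71 were among these 1302. Of these, 54 lay at promoters (76.1%, 64.5 to 85.4), against 62.6% of all 1302. A candidate explanation is that promoter DNA was recovered through other factors or open chromatin. The ETS word was 7.89 times as frequent at the promoter summits of this class as in their flanks, but also 4.09 times as frequent at promoter summits with CACGTG as in theirs. At the same summits of this class the permuted palindrome TGCGCA, a control word, was 7.48 times as frequent as in their flanks. The other control palindromes, ACCGGT and GTCGAC, were at 1.06 and 1.29 times. TGCGCA resembles part of the NRF1 word GCGCATGCGC, which was 21 times as frequent there, so it may not be a neutral control. ETS was at 13.2% of these summits against 7.02% of promoter summits with CACGTG (odds ratio 2.02, two-sided Fisher's exact adjusted p = 3.46e-09). The ETS fold over flanks alone still does not mark recovery through other factors, since it was raised in both classes. Recovery through other factors, open chromatin, and binding of USF1 to other words such as CACGCG were not separated, and no control library was analysed here.

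Chromosome 11 carried 1862 peaks, or 15.7 per Mb, and 32.7% of its genes had a promoter peak, against 21.3% of all genes. A richness in genes and favourable sites was argued against as the whole cause, since the odds of occupancy of its CACGTG sites against other autosomes were 1.67 times as high (95% interval 1.52 to 1.83) within strata of distance to a transcript start and flanking bases. Extra copies of the chromosome in this line may contribute, since weak distal background entries were 1.55 times as dense there as on the median autosome in replicate 1 and 1.61 times in replicate 2; open chromatin would also raise them. The X chromosome lay at the other end, with 2.31 peaks per Mb, an odds ratio of 0.529 and background densities of 0.574 and 0.595 times the median. Copy number itself was not measured, whether a control entered the calling of these entries is not known, and no biological explanation was tested.

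None of the 61 replication-dependent histone genes had a promoter peak in the optimal list. From other genes of like CpG content and CACGTG status, 17.0 bound genes were expected. The computed probability of 0 was 9.25e-10, but it treats each gene as independent. Histone genes can lie side by side, as H2ac20 and H2ac21 do, and may be lost together, so this value is too small. It cannot decide whether CpG content and few CACGTG words are the whole cause. The regions may also be missing from the lists before any threshold, since 3.33% of them (2 of 60) had a pooled entry within 1 kb, against 55.9% of genes of like CpG content without a peak. Reads shared between near-identical copies and a list of excluded regions both remain open as reasons; 70.6% of the 32-base words around these genes occur once in the genome, against 96.6% around matched genes. Only 4 histone genes had at least 95% such words, and 0 of these held an entry against 53.3% of 240 matched genes, too few to decide.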
